A study of Oncorhynchus gorbuscha with 37 samples.

How the data were processed

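The series measured messenger RNA in the cardiac ventricle of juvenile pink salmon (Oncorhynchus gorbuscha). Per the labels' protocols, embryos were kept in water carrying graded doses of Alaskan crude oil from fertilization until late organogenesis, then raised in clean water to about 8 to 10 months of age. Total polycyclic aromatic hydrocarbons (PAHs, the oil components tracked as the dose) ranged from 10 to 45 µg/L over the series. The labels give no concentration for each group. Total RNA was extracted with Trizol and made into libraries with the TruSeq RNA version 2 kit, per the labels.

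Each of the 37 libraries had a deposited table of read counts for the same 222598 contigs, the transcript fragments of a de novo assembly. The submitters' processing notes name CASAVA 1.7, Trimmomatic, Bowtie2, SAMtools and DESeq2, without saying which step each served. The assembler, the settings and the source of the contigs are not given in the sources used here. The deposited counts were whole numbers with no normalization, and the column for reads mapped to several contigs held 0 in every library. Names of the deposited tables record alignment, sorting and removal of duplicates. A cap on counts by duplicate removal was checked from the slope of log2 count on log2 library total. The median slope fell with abundance, from 1.32 at mean counts from 10 to 30, 1.28 from 30 to 100 and 1.17 from 100 to 300 to 1.03 for the 3363 contigs with mean counts from 300 to 1000, 0.844 for the 478 contigs from 1000 to 3000, and 0.316 for the 8 contigs at 6000 or more. Changes in the most abundant contigs may therefore be understated. Transcripts split over several contigs, and near-identical copies of a gene in this salmonid, could not be told apart by name.

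The contig names carry no gene name. Of the 222598 names, 0 matched the table of genes of the assembly OgorEven_v1.0, so contigs are reported by number. The lists of genes drawn up for this tissue and exposure (NKX family, innate immunity, cardiac and oil response genes) could not be tested. The rule for unnamed contigs took the 2 with the strongest rise and the 2 with the strongest fall, by adjusted p, in High against Control, or in the trend if none passed there. None passed there, so the trend was used, and these 4 contigs did not pass there either. The 4 contigs named for the Low group were chosen after their values were seen.

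Groups were taken from the exposure label: 8 Control, 5 Trace, 8 Low, 8 Medium and 8 High libraries. Replicate numbers only name the libraries. The labels do not say whether each library came from a separate fish, so p-values measure the spread between libraries, which may be partly technical.

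Counts were analysed in R 4.3.3 with edgeR 4.0.16. Contigs were kept by filterByExpr with its minimum count of 10, which left 57159 contigs holding 96.1% of the counts. Library sizes were scaled by TMM, with factors from 0.838 to 1.097. All 37 libraries entered a single model with a term for each group, and each contrast was tested by edgeR's quasi-likelihood test with robust estimation and Benjamini-Hochberg adjustment at a threshold of 0.05. The contrasts were each exposure level against Control, any difference among the 5 groups, a slope over scores 0 to 4 that stand for the order of the levels, and the mean of the 4 levels against Control. CPM values (counts scaled to a common library size) used the TMM-scaled library sizes, and log2 values carried a prior count of 2. Tests on library measures permuted the group labels 100000 times, and were two-sided.

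The procedure was tested on simulated counts for 57159 contigs with known changes in 200 of them. In High against Control it called 9% of 1.5-fold, 43.3% of 2-fold and 87.9% of 4-fold changes, with 4 false calls. In Trace against Control, with 5 exposed libraries, it called 3% of 1.5-fold, 34.3% of 2-fold and 84.8% of 4-fold changes. In Low against Control it called 11.9%, 49.3% and 89.4% of these, with 8 false calls. Every group was simulated with the same spread per contig, so false calls under the wider spread within the Low group were not tested. That spread came from all 37 libraries, Low included, so the shares called in the other comparisons may be too low.

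Alternatives were other size factors, no filter or a stricter filter, DESeq2 1.42.0, limma 3.58.1 (voom with quality weights), non-robust estimation, fits of only the groups compared, 1 surrogate variable from sva 3.50.0, the number in the sample titles as a block, and each library left out in turn. These, the groups, the tests and the rule for naming contigs were fixed before the data were examined. Fits without the Low group, fits without 3 libraries together, a regression on the scores, contrasts between exposure levels, a joint test of Low against both Control and High, and a contrast of Medium and High together against Control were added after the data were seen. Files were read with Python 3.11.15.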

Results

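Cardiac ventricle RNA was profiled in 37 libraries from juvenile pink salmon, of which 8 came from unexposed controls and 5, 8, 8 and 8 from fish exposed as embryos to crude oil at the Trace, Low, Medium and High levels. The series asked how exposure during heart development alters gene expression in the juvenile heart, with its title naming NKX family and innate immunity genes. Because the contigs carried no gene names, expression is given for numbered contigs.

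Total counts ranged from 2229615 in Medium replicate 3 to 8988029 in Control replicate 8, with a median of 5281514. By raw library totals, a contig with 3 counts stood at between 0.33 and 1.35 CPM, depending on the library. The TMM-scaled CPM used elsewhere differ somewhat, as 6 counts of contig_30130 in Medium replicate 3 stood at 3.04 CPM. Total counts did not differ between the 5 groups by more than the spread between libraries (permutation p = 0.615, Benjamini-Hochberg p = 0.82 over 4 library measures). The number of contigs detected gave a permutation p of 0.833. All pairs of libraries within a group differed by more than sampling noise, the closest pair having a chi-square of 2.62 per contig, so each library was counted once.

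**Figure D1:**
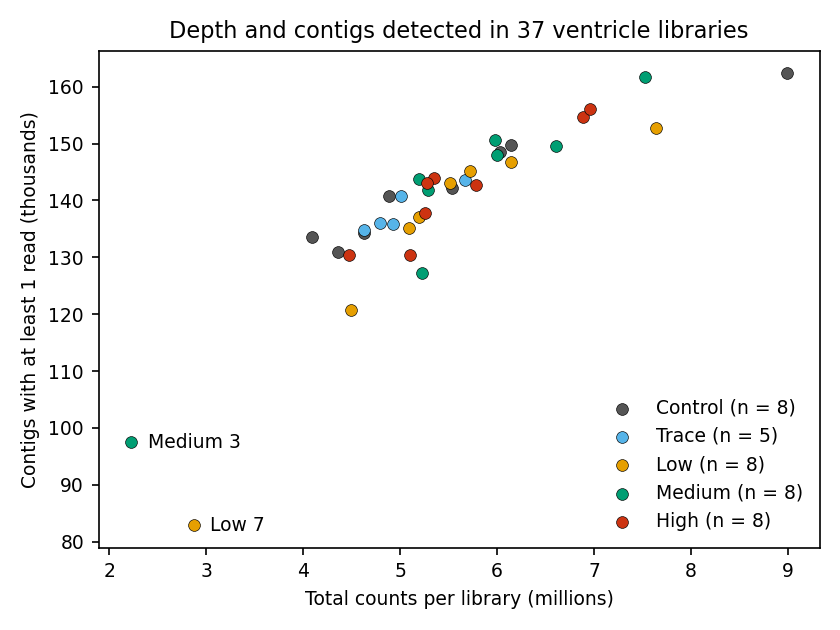
Total counts per library (x axis) against contigs with at least 1 read (y axis), with 1 point per library coloured by exposure level. Low replicate 7, at 2870393 counts, had the fewest contigs detected (82906), below Medium replicate 3 with 97503.

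Fish from the Low level had the clearest shift in ventricular expression. Relative to controls, 1119 contigs were higher and 254 were lower in the Low group (n = 8 and 8). The contigs that rose did so by a median log2 fold change of 1.23, and 746 of them rose more than 2-fold, 228 more than 4-fold and 20 more than 16-fold. The contigs that fell had a median log2 fold change of -0.95, with 114 beyond 2-fold and 10 beyond 4-fold. Of the contigs that rose, 136 had a mean below 1 CPM in controls, 584 lay between 1 and 10 CPM, and 399 were at 10 CPM or more.

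The contig with the strongest evidence of a rise, contig_30130, went from 8.41 ± 2.46 CPM in controls (SD, n = 8) to 33.6 ± 8.94 CPM in the Low group (SD, n = 8). Its log2 fold change was 1.99 (SE 0.22, adjusted p = 2.33e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the 8 Low libraries, from 24 to 50.9 CPM, all lay above the highest control at 12.5 CPM. Its mean was 6.85 CPM in Trace, 5.63 CPM in Medium and 6.55 CPM in High. Contig_23719 rose from 17.8 ± 2.81 CPM to 95.4 ± 75.3 CPM (SD, n = 8 each), with a log2 fold change of 2.42 (SE 0.31, adjusted p = 2.39e-05, same test). Its Low libraries spread from 21.2 to 214 CPM, so that the lowest of them stood at the level of the highest control. Contig_31585 fell from 30.7 ± 7.65 CPM to 10.1 ± 3.50 CPM (SD, n = 8 each), a log2 fold change of -1.60 (SE 0.19, adjusted p = 8.6e-06, same test). The 8 Low libraries, up to 16.1 CPM, were all below the lowest control at 20.3 CPM. Contig_113119 fell from 1.58 ± 0.585 CPM to 0.316 ± 0.144 CPM (SD, n = 8 each), on 0 to 3 counts per Low library, with a log2 fold change of -2.20 (SE 0.35, adjusted p = 0.000163, same test).

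**Figure D2:**
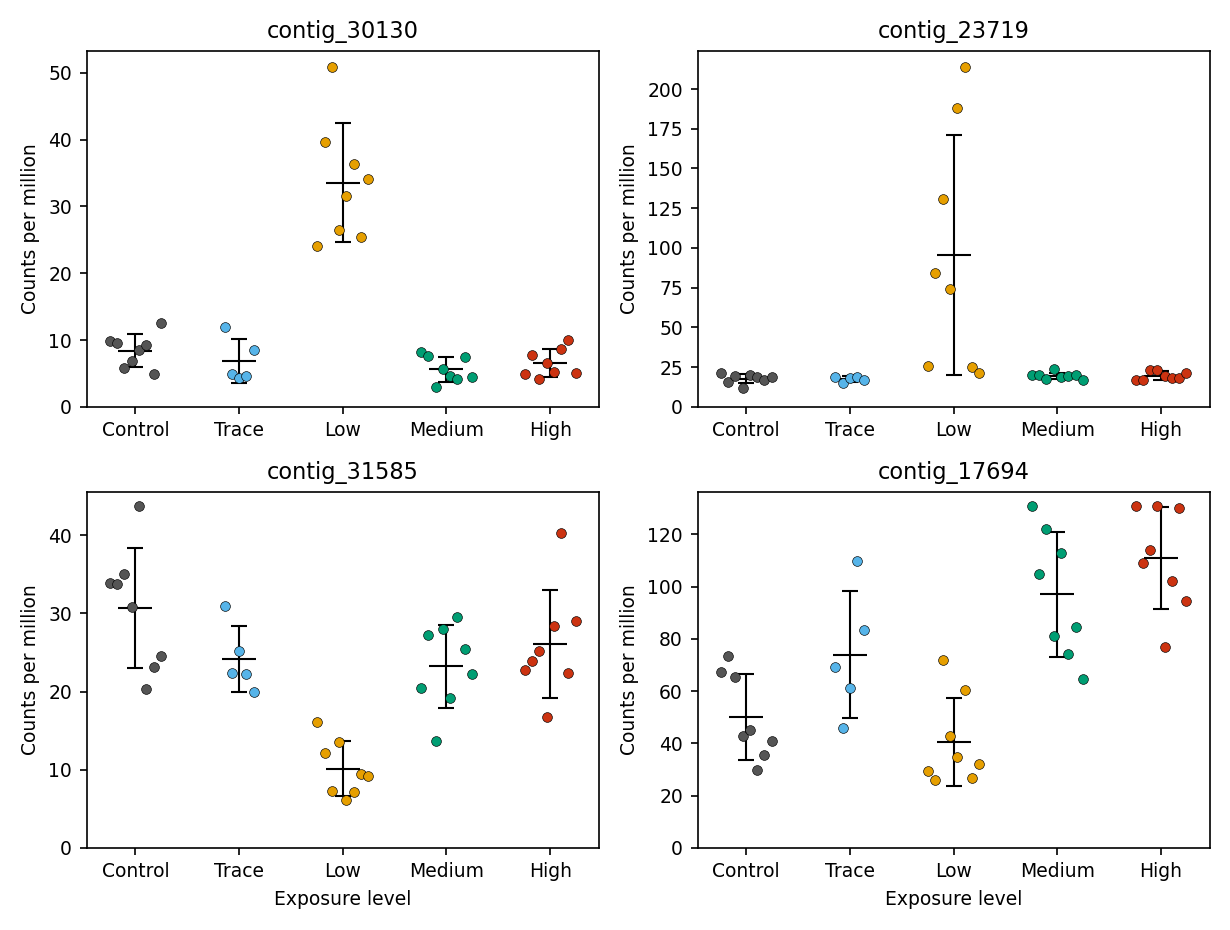
CPM (y axis) of 4 contigs in each library by exposure level (x axis); points are libraries, horizontal bars are means and error bars are SD. Contig_30130 and contig_31585 in the Low libraries lie outside the range of the controls, contig_23719 in the Low libraries spreads from 21.2 to 214 CPM, and contig_17694 has its highest means in Medium (97.0 CPM) and High (111 CPM).

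The rise was uneven among the 8 Low libraries. Summed over the 1119 contigs, expression was 16752 ± 747 CPM in controls and 33393 ± 11398 CPM in the Low group (SD, n = 8 each), ranging from 20088 to 50044 CPM among Low libraries. The sums were 18108 ± 1121 CPM in Trace (SD, n = 5), 18815 ± 1664 CPM in Medium and 18937 ± 1721 CPM in High (SD, n = 8 each). To measure each Low and Control library on contigs chosen without it, the fit was repeated with that library left out. The median log2 difference from controls over contigs called higher was then 0.22, 0.80, 1.49, 0.61, 1.66, 2.02, -0.38 and 0.23 in Low replicates 1 to 8, against -0.16 to 0.28 in the 8 controls. Over contigs called lower, it ran from -0.77 to -0.26 in the Low libraries and from -0.33 to 0.01 in the controls.

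**Figure D3:**
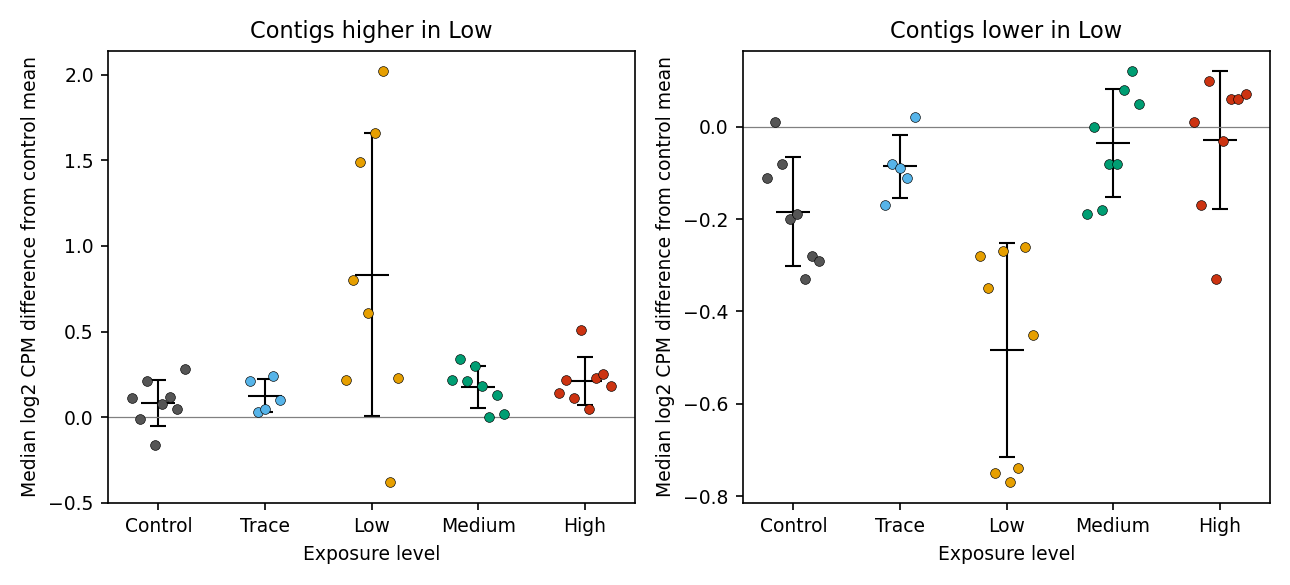
Median log2 CPM difference from the control mean (y axis) over contigs called higher (left) or lower (right) in the Low group, by exposure level (x axis); points are libraries, horizontal bars are means and error bars are SD. Low and Control libraries were scored on contigs called without them, and Trace, Medium and High libraries on the calls from all libraries; in the left panel 5 of the 8 Low libraries, from 0.61 to 2.02, exceed the highest library of the other groups at 0.51.

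The count for the Low level was 1373 contigs by edgeR's quasi-likelihood test, with 8812 at an unadjusted p under 0.05. It was 267 (249 higher, 18 lower) when only the Low and Control libraries were fitted, 2383 by DESeq2 and 2247 with 1 surrogate variable. The main fit shared a single estimate of spread over the 5 groups. The biological coefficient of variation within groups was 49.5% in Low (30% without Low replicate 7) and 19.6% to 27.5% in the others. The p-values of the main fit for Low may therefore be too small. It was 867, 794 or 709 without Low replicate 3, 5 or 6 respectively, and 2138 without Low replicate 7, the library whose expression profile stood farthest from the rest.

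Differences from the Low group were also found against the other exposure levels, in contrasts added after the data were seen. The Low group differed from Trace in 501 contigs, from Medium in 3164 and from High in 3388. Against the mean of these 3 levels, 3906 contigs were higher in Low and 1810 were lower. These contrasts used the main fit, so their p-values may likewise be too small. Of the 1373 contigs called against controls, 31.4% passed in the same direction against Trace, 70.5% against Medium, 66.7% against High and 90.8% against the mean of the 3, the same Low libraries standing in each contrast.

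At the Medium and High levels no contig passed the threshold in edgeR's quasi-likelihood test. The contig with the smallest p in the trend, contig_17694, averaged 50.1 ± 16.3 CPM in controls, 97.0 ± 24 CPM in Medium and 111 ± 19.7 CPM in High (SD, n = 8 each). Its log2 fold change was 0.95 (SE 0.21, adjusted p = 0.426) in Medium and 1.15 (SE 0.21, adjusted p = 0.0536) in High by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 8 High libraries ranged from 76.9 to 131 CPM and the 8 controls from 29.8 to 73.3 CPM. Contig_21608 had 2 ± 1.07 CPM in controls and 7.44 ± 3.64 CPM in High (SD, n = 8 each), with a log2 fold change of 1.93 (SE 0.42, adjusted p = 0.236, same test). Contig_34923 had 1.73 ± 0.983 CPM in controls and 0.559 ± 0.349 CPM in High (SD, n = 8 each), with a log2 fold change of -1.58 (SE 0.40, adjusted p = 0.454, same test). Contig_19185 was near 0 in some libraries and well expressed in others, from 0 to 19.9 CPM among controls. It had 0 counts in all 8 Medium libraries and at most 1 count in any High library, and no fold change is given for it.

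In High against Control, edgeR's quasi-likelihood test called 0 contigs, with 3149 (5.5%) at an unadjusted p under 0.05. In contrast, DESeq2 called 25, and limma voom with quality weights for the libraries called 218. In Medium against Control the 3 tools called 0, 4 and 3 contigs, with 2670 (4.7%) at an unadjusted p under 0.05 by edgeR. These shares are not to be read against 5%. Other splits of the libraries compared gave a median of 1181 such contigs for High and 1333 for Medium. For each level, 3 of 40 splits, the real one included, gave at least as many as the real split. The 8 High libraries all lay above the 8 controls for 36 contigs and all below for 11, where chance gives 4.44 contigs in each direction. Without Low replicate 7, the numbers at an unadjusted p under 0.05 were 5049 for High and 4125 for Medium. For Medium the contigs above and below all controls numbered 12 and 7, and for Low 48 and 46, with the same chance value. Such chance values are expected numbers only. Contigs are not independent, and how far these counts vary between splits was not tested.

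Trace libraries showed no called difference from controls. Contig_17694 averaged 74.1 ± 24.5 CPM in Trace (SD, n = 5), with a log2 fold change of 0.57 (SE 0.23, adjusted p = 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The test called 0 contigs, with 632 (1.1%) at an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. Other splits of the Trace and Control libraries gave a median of 964 contigs at an unadjusted p under 0.05. Of 40 splits, the real one included, 35 gave at least as many as the real split. The 5 Trace libraries all lay above the controls for 28 contigs and all below for 27, where chance gives 44.4 each.

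Over the ordered series, contig_17694 had a slope of 0.27 log2 units per level (SE 0.05, adjusted p = 0.0825) and contig_21608 a slope of 0.52 (SE 0.10, adjusted p = 0.0848), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Contig_34923 had a slope of -0.43 (SE 0.09, adjusted p = 0.122, same test), and contig_19185 also had an adjusted p of 0.122. The rise of contig_17694 was not steady along the series, as its mean in the Low group, 40.5 ± 17 CPM (SD, n = 8), lay below that in controls. The trend test in edgeR called 0 contigs, with 4348 at an unadjusted p under 0.05 (6563 without Low replicate 7). In the same trend, DESeq2 called 51, and limma voom with quality weights called 602. Without the Low group, a fit added after the data were seen, edgeR called 40 contigs in the trend and 7 in High against Control.

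Expression differed somewhere among the 5 groups for 1693 contigs by edgeR's quasi-likelihood test, with 8462 at an unadjusted p under 0.05. The count was 940 without Low replicate 6, 1049 without Low replicate 3 and 2650 without Low replicate 7, and it was 3722 by DESeq2 and 3996 by limma voom. The mean of the 4 exposure levels against controls gave 0 contigs in edgeR, DESeq2 and limma voom, with 2174 at an unadjusted p under 0.05 in edgeR.

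Fold changes of different levels share their controls, which alone makes them correlate across contigs, and contigs are not independent replicates. Medium and High fold changes had a correlation of 0.66, where simulated unchanged groups gave 0.50, and a covariance of 0.0542, where they gave 0.036. With the controls split 4 and 4 between the levels, the correlation was 0.24 (median over 70 splits, from 0.08 to 0.38). Low fold changes had a correlation of 0.20 with Medium and 0.22 with High, where simulated unchanged groups gave 0.49 and 0.50. Trace fold changes had a correlation of 0.26 with Low, 0.41 with Medium and 0.40 with High, against simulated values of 0.43, 0.43 and 0.44. Split controls brought the correlations of these 5 pairs to between -0.02 and 0.04. The simulation gave every group the same spread per contig, while spread within the Low group was wider than in the others. For these 5 pairs the covariances, from 0.023 to 0.0289, lay below the simulated 0.0359 or 0.036. The simulated values may therefore be too high. A correlation below its simulated value is not read as agreement less than chance.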

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

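The tests of explanations in this part, the splits of the samples included, had their criteria written down only after the results were seen.

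The Low group differed from the mean of Trace, Medium and High in 5716 contigs (edgeR's quasi-likelihood test), tested directly, and its rise against controls was uneven among libraries, with left-out median log2 differences from -0.38 to 2.02. A one-source fit to the 136 risen contigs below 1 CPM in controls left a Pearson statistic of 9.99 per degree of freedom. The value was 9.95 without Low replicate 7. In the other groups the same fit, on contigs of the same abundance, reached at most 5.38, which argues against admixture of a single constant source of RNA. Those contigs were not chosen for having risen and came from groups with less spread. A source that varied in make-up therefore cannot be told from several sources. Library depth as the whole cause is argued against, because 5 of the 7 Low libraries with others within 10% of their total exceeded all of those on contigs called without them. As the sole cause, a response that grows with exposure level is argued against for 525 contigs beyond both Control and High in Low. They lay in the same direction in both edgeR contrasts (465 higher, 60 lower), by the larger p with Benjamini-Hochberg over all 57159 contigs. This count and the 5716 come from the main fit, whose p-values for Low may be too small. With only the Low and Control libraries fitted, 267 contigs passed against Control. The joint test was run only in the main fit. An event confined to Low fish or libraries may give the same pattern. Over all contigs that rose, a response that grows with exposure level stays open. Left-out Low scores (0.83 ± 0.83, SD, n = 8) and High scores (0.21 ± 0.14, SD, n = 8) gave an exact two-sided permutation p of 0.0622. Low replicate 7, at -0.38, was the lowest of these Low scores, and the permutation test was not repeated without it. An effect particular to the Low level and an event shared by some Low fish or libraries also stay open. Both are untested because the labels give no rearing unit or batch.

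By the number of calls, chance is argued against for Low, since of 40 splits of the Low and Control libraries only the real one gave as many. This share, 1 of 40, is the lowest that 40 splits can give, so it does not exclude chance. The real split gave 1373 contigs, against 898 in the highest other split. That split kept Low replicates 2 to 6 together with Control replicates 3, 4 and 5, which points to a structure of the samples within the Low group, and it had 9905 contigs at an unadjusted p under 0.05 against 8812 in the real split, so that by this measure 2 of 40 splits gave as many and chance could not be excluded. For any difference among the 5 groups chance is argued against by the same lowest share (1 of 40 splits, with 1693 contigs against 609). For the other comparisons the real count was 0, which every one of the 40 splits (40 of 40) must reach, so the counts of calls say nothing about chance. The highest other splits gave 10 contigs for Trace, 1 for Medium, 0 for High, 77 for the trend and 17 for all exposed against controls. By contigs at an unadjusted p under 0.05 in edgeR, as many as in the real split were found in 35 of 40 splits for Trace, 3 for Medium, 3 for High, 5 for the trend and 16 for all exposed, so chance could not be excluded there.

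Low replicate 7 stood apart from the other libraries, with 82906 contigs detected against 120674 in the nearest Low library. Lower depth is argued against, because after thinning to 2229615 counts it had 76961 contigs, against 97628 in the nearest Low library and at least 97503 in all others. A graded axis of library complexity shared with other libraries remains a candidate explanation: across the other 36 libraries, position along its axis correlated with contigs detected after thinning at r = -0.63 (permutation p = 0.00011, Benjamini-Hochberg p = 0.00022 over both) and rho = -0.50 (permutation p = 0.002, Benjamini-Hochberg p = 0.002), with r = -0.51 without the 2 farthest libraries. With group means removed r was -0.67, and within groups it was 0.04 in Control, -0.63 in Low, -0.81 in Medium and -0.79 in High, and it was not computed for Trace, with 5 libraries, so the relation did not hold within Control. Part of this relation may be built in, since Low replicate 7 had 0 counts in 8606 of the 57159 tested contigs and these help define its axis. Another tissue or a wrong label cannot be told apart from an unusual ventricle library, as no contig carries a gene name. In Low replicate 7, 62.0% of contigs lay beyond all other libraries (chance 5.4%).

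Few contigs passed outside the Low comparison. Spread inflated by the Low libraries stays open as a partial cause: without the Low group High against Control gave 7 contigs, Medium and Trace 0 and the trend 40, and contigs at an unadjusted p under 0.05 went from 3149 to 5530 in High, from 2670 to 4629 in Medium and from 632 to 1251 in Trace. Changes of under 2-fold may also account for part of it, as 9.0% of simulated 1.5-fold and 43.3% of simulated 2-fold changes were called in High against Control. The simulation took its spread from all 37 libraries, Low included. The biological coefficient of variation was 30% over all of them, against 24.3% within High and 23.2% within Control. These shares may therefore be too low, and this explanation cannot be told apart from the spread added by Low. The 218 contigs called by limma voom in High leave open how much the choice of test contributes. That fit also weighted each library, with 0.069 for Low replicate 7 and 0.309 for High replicate 4. The test and the weights cannot be told apart here.

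Other single libraries lay far from their group by Dixon's criterion, which chance meets in about 1 of 20 groups; 9 values in 70 tested groups did so, where chance gives 3.5. Control replicate 8 had 8988029 total counts, against 6142762 in the next highest control. Medium replicate 3 had 2229615 total counts, against 5201902 in the next lowest, and its 10 most abundant contigs held 2.58% of counts, against 1.60% in the next highest. High replicate 4 had a median log2 difference of 0.51 over contigs higher in Low, against 0.25 in the next highest. Low replicate 7 had a median log2 difference of -1.73 over contigs lower in Low, against -1.05 in the next lowest. Those contigs were called with Low replicate 7 in the fit. On contigs called without it, its value was -0.26, so the outlying value did not hold there. High replicate 2 had 0.199 CPM of contig_19185, which is 1 count, against 0 in the other High libraries. Control replicate 6 had 3.91 CPM of contig_34923, against 2.11 CPM in the next highest control.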

How the results depend on the processing

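Fits without the Low group, without 3 libraries together and by regression on the scores were chosen after seeing the data. Counts are contigs past the threshold in edgeR unless another tool is named, and the cause of a change was not tested unless given.

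Trace against Control and all exposed against Control gave 0 contigs under every setting run, DESeq2 and limma voom included. With each library left out in turn, these comparisons had 578 to 1078 and 1702 to 3414 contigs at an unadjusted p under 0.05.

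For Low against Control (1373), the count was 2247 with 1 surrogate variable, 2383 by DESeq2, 2354 at an adjusted p under 0.10, 267 with only those groups fitted, and 2507 without Low replicate 7, Medium replicate 3 and High replicate 4. Leaving out each library gave 709 (without Low replicate 6) to 2138 (without Low replicate 7). For any difference (1693), the count was 3112 with 1 surrogate variable, 3722 by DESeq2, 2762 at an adjusted p under 0.10, 3996 by limma voom and 2756 without those 3 libraries. Leaving out each library gave 940 to 2650.

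For Medium against Control (0), DESeq2 called 4 and limma voom 3, and leaving out each library gave 0 to 1. For High against Control (0), the count was 1 with 1 surrogate variable, 2 with DESeq2 size factors, 25 by DESeq2, 2 at an adjusted p under 0.10, 218 by limma voom, 1 without a filter, 4 with only those groups fitted and 7 without the Low group. Leaving out each library gave 0 to 4. For the trend (0), the count was 36 with 1 surrogate variable, 51 by DESeq2, 4 at an adjusted p under 0.10, 602 by limma voom, 1 without a filter and 40 without the Low group. Leaving out each library gave 0 to 16. A contig passed in 13 of the 37 left-out fits for High and in 8 of 37 for the trend. The highest values for Medium, High and the trend came without Control replicate 3.

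With the number in the sample titles as a replicate block, edgeR called 0 contigs in Low against Control (3536 at an unadjusted p under 0.05) and 0 for any difference (2978 at an unadjusted p under 0.05). No consistent pairing by these numbers was seen, as 4 of 14 same-numbered pairs had deviations correlated above 0.1. The median was 0.07 (-0.006 for other pairs), with a range from -0.132 to 0.38. A weak pairing cannot be excluded, since this difference was not tested. The labels do not say what the numbers mean. The block left 8 residual degrees of freedom, and under it none of the 4 contigs named for Low passed, with log2 fold changes of 1.75 (contig_30130), 1.55 (contig_23719), -0.94 (contig_31585) and -1.81 (contig_113119).

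With split controls, the correlation of fold changes was -0.02 for Trace with Low, 0.04 for Trace with Medium, 0.01 for Trace with High, -0.02 for Low with Medium, -0.01 for Low with High and 0.24 for Medium with High.

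For the 8 named contigs, 1895 of the values over other settings kept their direction and their side of the threshold, 41 newly passed it, 4 no longer passed it and 12 changed sign without a call. Contig_30130, contig_23719, contig_31585 and contig_113119 passed in Low against Control in 47 of 48 settings, and contig_17694 in High against Control in 14 of 49. Sums per assembly cluster and tests of gene lists were not run, since the contig names show neither clusters nor genes. Depth limits contigs near 3 counts, which is up to 1.35 CPM by raw library totals and somewhat more by TMM-scaled CPM.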

Other observations

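The test of presence by group, the contrast of Medium and High together, and the use of the split controls to weigh the hypothesis were chosen after the data were seen. Some contigs were at 0 in several libraries and well expressed in others. There were 62 contigs with 0 counts in at least 6 libraries and at least 5 CPM in at least 6 others, and a median of 11 libraries lay in between. Contig_19185 was similarly variable, with 0 to 19.9 CPM among the 8 controls. Over the 62 contigs, Fisher's exact test of presence by exposure group gave 8 (12.9%) at an unadjusted p under 0.05 and 0 after Benjamini-Hochberg adjustment.

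Spread between libraries was widest in the Low group, though the difference between levels was not tested. The biological coefficient of variation, edgeR's common estimate within a group, was 23.2% in Control, 19.6% in Trace, 49.5% in Low, 27.5% in Medium and 24.3% in High. Without Low replicate 7, it was 30% in Low. The median SD of log2 CPM was 0.711 in Low, 0.408 in Low without replicate 7 and 0.419 in Medium, so the wider spread rested largely on that library.

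A hypothesis is that the Medium and High levels share part of a response. Their fold changes had a correlation of 0.66 across contigs, where unchanged groups, simulated with the same spread in every group, gave 0.50. The shared control libraries as the only cause are argued against, since with the controls split 4 and 4 the correlation was above 0 in all 70 splits, with 0.08 as the lowest. Rearing or library batches shared by both levels stay open, since the labels give none. Deviations of Medium replicate 3 and High replicate 4 from their group means had a correlation of 0.38. The fold-change correlation was not computed without these libraries, so their part in it stays open, and splitting the controls cannot address it. Medium and High together against Control gave 3 contigs, all higher, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, among them contig_17694 (log2 fold change 1.05, adjusted p = 0.0346), and 13 contigs without the Low group, 11 higher and 2 lower. Against the mean of Control and Trace the same test called 0 contigs, with 3906 at an unadjusted p under 0.05, and no other tool was run on it.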
